A study of Marchantia polymorpha with 36 samples.

How the data were processed

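RNA was taken from entire 3-week-old thallus plants of 4 lines under 3 treatments, with 3 libraries in each of 12 groups. Per the labels, RNA was extracted with a NucleoSpin RNA kit and strand-specific mRNA libraries were made with a TruSeq stranded kit. The aligner, the genome build, the annotation and the handling of strands are not given in the sources used here. The time point called t6LL in the sample labels is the mock treatment that the protocol calls t6GL.

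The deposited files hold, per the file headers, counts of reads per gene, given by the authors as raw counts split into exon and intron reads and into uniquely placed and all reads. They also hold TPM and RPKM values computed by the authors, which were not used here. The counts used were all reads assigned to a gene. Total gene reads per library ran from 32677231 to 62050636. Uniquely placed reads made up 98.5 to 99.3% and intron reads 3.54 to 5.75% of gene reads. In GATA1ox t0 replicate 3, the library with the fewest reads, the V-linked gene MpVg01240 alone took 18.4% of reads. No 2 libraries of a group were copies of each other: the chi-square per gene between replicates was 4.63 or more over 36 pairs, above the value of 1 that counting noise gives.

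Genes were filtered with filterByExpr and scaled with TMM factors in edgeR 4.0.16 under R 4.3.3. A quasi-likelihood model with robust=TRUE and a mean per group was fitted to all 36 libraries, leaving 15583 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistic of this test. Group values are normalised CPM (read counts scaled to the TMM-adjusted library size), mean ± SD over 3 libraries. The comparisons were t6HL against t6LL in each line, each line against BoGa over t0 and t6LL and at t6HL, the interaction of line and high light, and t6LL against t0 in BoGa. The lane numbers come from the names the authors gave their files.

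The size of the response to high light was the median log2 fold change over genes called in the mean response of the 4 lines. Its replicate values use an offset equal to the fit's prior of 0.125 reads. That offset was chosen after seeing the data, because a first offset of 0.5 CPM gave replicate ranges that left out the fitted medians: 23.6% of the rising genes lay under 1 CPM. For overlaps between lines that share the BoGa libraries, 20 sets of unchanged libraries were simulated, and BoGa libraries were also divided by time point so that each line had its own.

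Gene symbols came from a RefSeq gene table whose assembly is named there as MpTak2_v7.1, paired with the gene IDs by locus number and kept where the gene lengths differed by no more than 10%. Of 19472 genes in the files 17671 were paired by number and 16690 of these (94.4%) met the length limit, against 8.96% when the pairing was shifted by 1 gene. Symbols were found for 2909 genes, and 186 symbols were left out for length. Whether the coordinates printed here belong to that build is not given in the sources used here.

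Of the gene lists, 21 were planned before the data were examined and 11 were added after the spelling of the symbols had been read, before any comparison: LEA and dehydrin, dirigent, pathogenesis-related, 2-oxoglutarate dioxygenase, cupin, bHLH, O-methyltransferase, pentatricopeptide repeat, fatty acid desaturase, NBS-LRR and autophagy genes. Planned lists with fewer than 3 named members were not tested. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over 448 tests of 32 lists in 14 comparisons, and again with an estimated correlation and with fry.

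The genes named were picked by a rule set before the data were examined. For each comparison it took the 6 largest changes in each direction among called, named genes with a mean of at least 5 CPM and no overlap between the libraries, and up to 4 called members of each list that was called or had at least 3 called members, up to 20 per comparison. Genes with few reads on 1 side are given as CPM and not as fold changes. U-linked and V-linked genes were counted at 1 CPM or more of uniquely placed reads.

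The alternatives were RLE size factors, no filter on low counts, a replicate block, uniquely placed reads, a fold of at least 2, fits on the compared groups alone, DESeq2 1.42.0, t0 as the baseline, each growth light time alone, and leaving out each library in turn. Exon reads, autosomal genes alone and leaving out MpVg01240 were chosen after seeing the data. By a rule that all 3 correlations exceed 0.1, replicate numbers paired the libraries in 1 of 29 pairs of groups, which mix time points. This pair was BoGa and gata1-2 at t6HL, where the deviations of same-numbered libraries from their group means correlated across genes at 0.60, 0.16 and 0.37 (mean of other numbers -0.18). Within t6LL, BoGa and GATA1ox gave 0.095, 0.30 and 0.22 (other numbers -0.10), whereas BoGa and gata1-2 gave -0.020, 0.021 and -0.11 (other numbers 0.017). A pairing within a time point was therefore not excluded, and a block within each time point was not fitted. The labels do not say that a number marks a shared culture or day. The replicate block for the list tests was also chosen after seeing the data. The pipeline was tested on simulated data: for 2-fold changes it recovered 68.7% of genes in a response to high light, 85.1% in a line difference at growth light and 67.2% in an interaction, with 2, 12 and 5 false calls. Only 67 of 15583 genes were changed 2-fold in each simulation, so these shares do not carry over to comparisons in which many genes change. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.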

Results

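The transcriptome of the liverwort Marchantia polymorpha was measured in entire 3-week-old thallus plants of 4 lines: BoGa, labelled as the wild type, the mutant lines Mpb-gata1-1 and Mpb-gata1-2 (gata1-1 and gata1-2 below), and the line MpB-GATA1ox (GATA1ox below), whose name marks overexpression. B-GATA1, the gene the lines are named after, belongs by its name to the GATA family of zinc finger transcription factors. Each line was sampled before a light shift (t0), after 6 h of high light at 1200 µmol m-2 s-1 (t6HL) and after a 6 h mock treatment at the growth light of 60 to 70 µmol m-2 s-1 (t6LL). The 12 groups held 3 libraries each, 36 in all. Total gene reads per library ran from 32677231 to 62050636, and 15583 genes had enough reads to be tested. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples only. All t0 libraries were sequenced in lane 1 and all t6HL libraries in lane 2, while the t6LL libraries were in lane 1 for BoGa and gata1-1 and in lane 2 for gata1-2 and GATA1ox.

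Which named gene is B-GATA1 is not given in the sources used here, so the 3 named GATA genes are reported together and none is taken as the target. At t0 MpGATA4 (Mp7g03490, chromosome 7, 4342060 to 4345887) stood at 109 ± 3.24 CPM (normalised read count scaled to library size, mean ± SD, n = 3) in BoGa, 195 ± 11.2 in gata1-1, 171 ± 11.1 in gata1-2 and 211 ± 76.0 in GATA1ox. Averaged over t0 and t6LL it was higher than in BoGa in all 3 lines, with log2 fold changes of 0.73 ± 0.15 (SE), 0.56 ± 0.15 and 0.76 ± 0.15 (edgeR adjusted p = 0.00019, 0.0025 and 0.00023). With the t6LL libraries alone the calls for gata1-2 (log2 fold change 0.48, adjusted p = 0.074) and GATA1ox (0.57, adjusted p = 0.064) were lost. In high light the line GATA1ox kept 166 ± 42.6 CPM against 56.1 ± 11.5 in BoGa, a log2 fold change of 1.56 ± 0.22 (edgeR adjusted p = 3.3e-06). The value for gata1-1 in high light was -0.69 ± 0.21 (edgeR adjusted p = 0.0076), a call that was lost without BoGa t6HL replicate 1 (-0.49, adjusted p = 0.073). MpGATA2 (Mp1g03950) was lower in both mutant lines at growth light, by -0.77 ± 0.13 and -0.69 ± 0.13 (edgeR adjusted p = 2.0e-05 and 6.7e-05). It was at 0.31 ± 0.13 in GATA1ox (edgeR adjusted p = 0.066, and 0.00022 in a fit on the compared libraries alone). In high light it was at -1.24 ± 0.19 in gata1-1 (edgeR adjusted p = 5.0e-06) and -0.34 ± 0.19 in gata1-2 (edgeR adjusted p = 0.15, and 0.045 without BoGa t6HL replicate 3). In GATA1ox it was higher there, by 0.76 ± 0.19 (edgeR adjusted p = 0.0028, and 0.056 in a fit on the compared libraries alone). MpGATA1 (Mp1g05310) at growth light was at 0.05 ± 0.05 in gata1-1, -0.14 ± 0.05 in gata1-2 and -0.03 ± 0.05 in GATA1ox (edgeR adjusted p = 0.50, 0.037 and 0.77). The call in gata1-2 was lost with t0 alone (-0.16, adjusted p = 0.097) and with t6LL alone (-0.11, adjusted p = 0.28). It was also lost without gata1-2 t0 replicate 1 (adjusted p = 0.068) or 2 (adjusted p = 0.075) and without gata1-2 t6LL replicate 1 (adjusted p = 0.054) or 3 (adjusted p = 0.079). In high light MpGATA1 was at -0.50 ± 0.08 in gata1-1, -0.19 ± 0.08 in gata1-2 and -0.07 ± 0.08 in GATA1ox (edgeR adjusted p = 4.1e-06, 0.047 and 0.57). That call in gata1-2 was lost without BoGa t6HL replicate 1 (adjusted p = 0.33) or 3 (adjusted p = 0.058) or gata1-2 t6HL replicate 3 (adjusted p = 0.34). All 3 genes were expressed in every library of the mutant lines, so these values do not check the genotype labels.

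**Figure D1:**
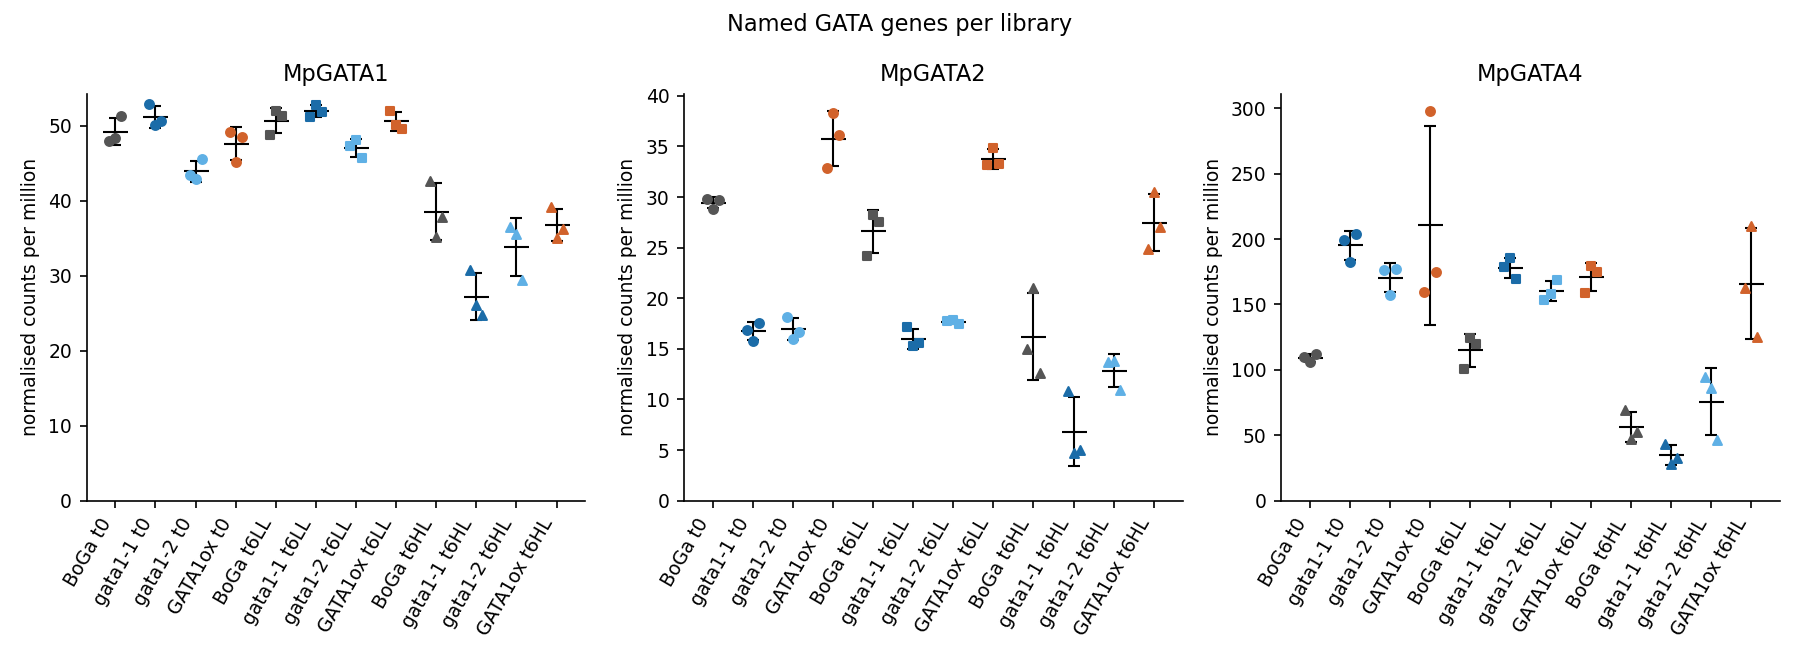
Normalised CPM of MpGATA1, MpGATA2 and MpGATA4 in each library (points, 3 per group), with the group mean and SD (black), by line and treatment. MpGATA4 in high light stood at 166 CPM in GATA1ox against 56.1 CPM in BoGa.

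The libraries of gata1-1 differed from all others on the sex chromosomes. Among 47 genes on the U chromosome, which female plants carry, 30 reached 1 CPM of uniquely placed reads in each of the 9 gata1-1 libraries, against 1 or 2 in each library of the other lines. On the V chromosome, which male plants carry, 5 to 10 of 146 genes reached that level in gata1-1, against 31 to 33 in BoGa, 30 to 32 in gata1-2 and 31 to 40 in GATA1ox. MpBPCU (MpUg00370), a U-linked gene of sex determination, stood at 27.8 ± 0.24 CPM in gata1-1 and 0.022 ± 0.022 CPM in BoGa at t6LL (mean ± SD, n = 3). MpRAB11AX (MpUg00350) stood at 307 ± 9.64 CPM in gata1-1 and 0.060 ± 0.040 CPM in BoGa at t0. Every comparison of gata1-1 with BoGa therefore also compares plants that differ in the sex chromosome expressed.

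**Figure D2:**
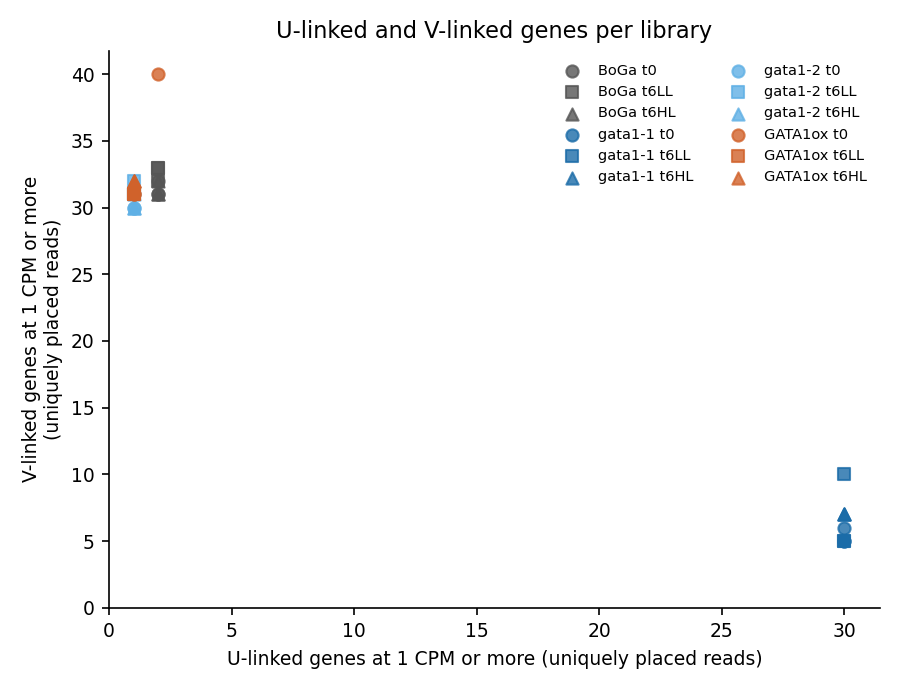
Number of U-linked genes (horizontal axis) and V-linked genes (vertical axis) at 1 CPM or more of uniquely placed reads, 1 point per library, coloured by line and shaped by treatment. The 9 gata1-1 libraries sit at 30 U-linked genes and 5 to 10 V-linked genes, apart from the other 27.

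The response to high light, t6HL against t6LL within a line, was led in BoGa by genes for late embryogenesis abundant (LEA) proteins and dehydrins, small hydrophilic proteins known from drying tissues. Of the 65 such genes tested, 53 rose, 4 fell and 8 did not pass the test, with a median log2 fold change of 3.98. MpDHN2 (Mp4g06390, chromosome 4, 7103110 to 7104084) rose from 20.1 ± 2.32 to 2451 ± 444 CPM, a log2 fold change of 6.93 ± 0.28 (SE), and MpDHN3 rose by 7.09 ± 0.34. Of 29 genes that remove reactive oxygen species 16 rose and 4 fell (16 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0545 and adjusted p = 0.712 with an estimated correlation). Among the 16, the catalase gene MpCAT1 rose by 5.26 ± 0.45, the dehydroascorbate reductase gene MpDHAR4 by 3.08 ± 0.25 and the glutathione peroxidase gene MpGPX2 by 1.26 ± 0.12. Genes of the cell cycle fell, 35 of 47 (35 adjusted over the list alone), among them the histone genes MpH2B.4 at -2.31 ± 0.22 and MpH4e at -1.56 ± 0.10 and MpRBR, the retinoblastoma-related regulator of cell division, at -0.99 ± 0.07. The largest drops among named genes were MpXIP (Mp3g14380), of an aquaporin subfamily, at -4.14 ± 0.30, and MpCE8.10, of the pectin methylesterase family, at -3.65 ± 0.23. The largest edgeR adjusted p value of the genes named here was that of MpH2B.4, 7.0e-10.

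In all, 9288 genes changed in BoGa in high light, 4705 higher and 4583 lower. Of these, 3371 changed at least 2-fold, 2283 up and 1088 down. The LEA list (camera adjusted p = 3.7e-14) and the cell cycle list (camera adjusted p = 4.4e-06) moved against the other genes with a preset correlation between genes. Both calls were lost otherwise, at adjusted p = 0.712 with an estimated correlation. The LEA list was written after the gene symbols had been read, before any comparison. In BoGa and gata1-1 the t6HL and t6LL libraries lay in different lanes, whereas in gata1-2 and GATA1ox both lay in lane 2, and the last 2 lines give the response within a lane.

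The other lines changed 10940 genes (gata1-1, 5408 higher and 5532 lower), 9962 genes (gata1-2, 4798 and 5164) and 9570 genes (GATA1ox, 4978 and 4592) in high light. In all 4 lines 2936 genes rose and 3010 fell, where independent lists would share 161 and 159, and 656 genes were called in opposite directions in at least a pair of lines. The log2 fold changes correlated across genes between lines at r = 0.78 to 0.88 (genes are not independent replicates). LEA genes rose in each line: 54 of 65 in gata1-1 (median 3.52), 48 in gata1-2 (median 1.72) and 53 in GATA1ox (median 5.63), with camera adjusted p = 3.0e-10, 4.3e-09 and 1.9e-12. With an estimated correlation these gave adjusted p = 0.712 for gata1-1, adjusted p = 0.724 for gata1-2 and adjusted p = 0.712 for GATA1ox. MpDHN2 rose by 6.91 ± 0.28 in gata1-1, 7.21 ± 0.29 in gata1-2 and 7.44 ± 0.29 in GATA1ox. In GATA1ox the catalase gene MpCAT1 went from 0.058 ± 0.042 to 71.8 ± 51.0 CPM (mean ± SD), against 1.34 ± 0.54 to 52.2 ± 18.2 CPM in BoGa. Cell cycle genes fell in each line, 32 of 47 in gata1-1, 32 in gata1-2 and 31 in GATA1ox, the same numbers adjusted over the list alone (camera adjusted p = 0.00079, 0.00017 and 0.00014 and adjusted p = 0.724 with an estimated correlation in each).

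**Figure D3:**
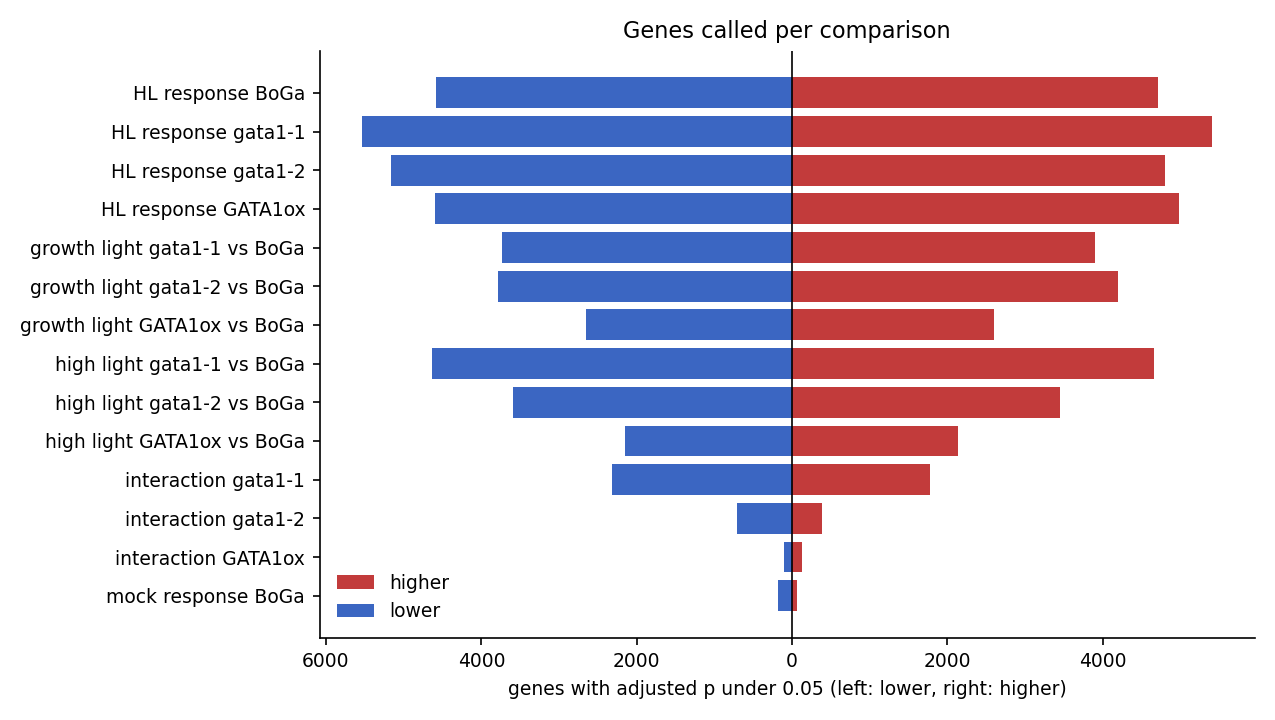
Number of genes past edgeR's adjusted p threshold in each comparison, higher to the right in red and lower to the left in blue. The responses to high light hold 9288 to 10940 genes, and the mock response of BoGa holds 238.

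Oil body genes, mostly terpene synthase-like genes of the cells that store terpenoids in liverworts, fell in high light in the mutant lines. In gata1-2 18 of 25 fell (18 adjusted over the list alone, camera adjusted p = 0.00026 and adjusted p = 0.712 with an estimated correlation), with MpFTPSL1 at -2.62 ± 0.24 and MpFTPSL6 at -2.16 ± 0.21. In gata1-1 14 of 25 fell (14 adjusted over the list alone, camera adjusted p = 0.028 and adjusted p = 0.724 with an estimated correlation), among them MpC1HDZ, a regulator of oil body cell identity, at -2.09 ± 0.25. Class III peroxidase genes fell as well, 60 of 128 in gata1-1 (54 adjusted over the list alone, camera adjusted p = 0.032 and adjusted p = 0.829 with an estimated correlation) and 62 in gata1-2 (60 adjusted over the list alone, camera adjusted p = 0.021 and adjusted p = 0.816 with an estimated correlation). MpPOD68 fell by 4.03 ± 0.31 on the log2 scale in gata1-1 and by 4.65 ± 0.34 in gata1-2. Polyphenol oxidase genes fell in gata1-2, 33 of 51 (33 adjusted over the list alone, camera adjusted p = 0.030 and adjusted p = 0.724 with an estimated correlation). All 5 named HSP90 family genes, which encode chaperones, rose in gata1-1 (5 adjusted over the list alone, camera adjusted p = 0.039 and adjusted p = 0.724 with an estimated correlation). Genes that remove reactive oxygen species rose in GATA1ox, 16 of 29 with 5 lower (16 and 5 adjusted over the list alone, camera adjusted p = 0.035 and adjusted p = 0.712 with an estimated correlation), with MpPRX1 at 1.23 ± 0.09 and the glutathione reductase gene MpGR1 at 0.88 ± 0.07. Of lists added after the symbols had been read, bHLH transcription factor genes fell in gata1-1 (22 of 37, camera adjusted p = 0.030) and GATA1ox (20, camera adjusted p = 0.047), at adjusted p = 0.724 with an estimated correlation. NBS-LRR genes fell in GATA1ox (11 of 17, camera adjusted p = 0.026 and adjusted p = 0.712 with an estimated correlation), and autophagy genes rose in gata1-2 (12 of 20, camera adjusted p = 0.044 and adjusted p = 0.738 with an estimated correlation). A list called in some lines is not thereby shown to differ between lines; the tests of the difference follow with the interactions.

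The size of the response was read from the 6282 genes that rose and the 6223 that fell in the mean over the 4 lines. For the rising genes the median log2 fold change was 0.71 in BoGa (0.62 to 0.80 over the 3 replicates), 0.90 in gata1-1 (0.84 to 0.90), 0.70 in gata1-2 (0.59 to 0.77) and 0.76 in GATA1ox (0.59 to 0.83). The replicate range of gata1-1 lay above that of BoGa, and those of the other lines overlapped it. Each replicate value sets a t6HL library against the mean of the 3 t6LL libraries. The ranges therefore leave out the spread of the baseline, and ranges that lie apart are no test of a difference between lines. For the falling genes the medians were -0.49, -0.64, -0.57 and -0.50, and over all of these genes only the range of gata1-1 (-0.67 to -0.61) lay apart from that of BoGa (-0.56 to -0.45). Among genes that fell at least 2-fold in the mean, the range of gata1-2 (-1.83 to -1.50, median -1.59) also lay apart from that of BoGa (-1.425 to -1.18, median -1.22), as did that of gata1-1 (-1.64 to -1.43, median -1.52). An exact permutation test of 3 against 3 replicates cannot go below p = 0.10 (two-sided), so none was run.

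At growth light, over t0 and t6LL, the line gata1-1 was marked by lower expression of lipoxygenase, phenylpropanoid and pathogenesis-related genes. The lipoxygenase gene MpLOX4 (Mp5g21680) stood at 0.85 ± 0.32 CPM at t0 against 87.6 ± 10.3 in BoGa, a log2 fold change of -6.33 ± 0.30 (SE) over both times. MpLOX15 and MpLOX16 were at -3.34 ± 0.23 and -2.84 ± 0.19, and 11 of the 19 lipoxygenase and jasmonate genes were lower and 4 higher (11 and 4 adjusted over the list alone, camera adjusted p = 0.012 and adjusted p = 0.712 with an estimated correlation). Of 64 phenylpropanoid and flavonoid genes 35 were lower and 11 higher (37 and 12 adjusted over the list alone, camera adjusted p = 0.00031 and adjusted p = 0.712 with an estimated correlation), with MpPAL-like2, named after phenylalanine ammonia-lyase, at -1.62 ± 0.13 and MpDFR-like16 at -2.16 ± 0.12. MpR2R3-MYB1 was at -4.81 ± 0.18. LEA genes were higher, 44 of 65 with 7 lower (median 1.04, camera adjusted p = 0.0015 and adjusted p = 0.74 with an estimated correlation). In total 7631 genes differed from BoGa, 3893 higher and 3738 lower, and 5057 with the t0 libraries alone, all from lane 1.

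Smaller lists in gata1-1 at growth light moved as follows. Oil body genes were lower in 11 of 25 (13 adjusted over the list alone, camera adjusted p = 0.038 and adjusted p = 0.724 with an estimated correlation), and WRKY transcription factor genes in 7 of 13 (7 adjusted over the list alone, camera adjusted p = 0.038 and adjusted p = 0.724 with an estimated correlation). Pathogenesis-related genes were lower in 15 of 29 (camera adjusted p = 0.0013) and NBS-LRR genes in 10 of 17 (camera adjusted p = 0.026), each at adjusted p = 0.712 with an estimated correlation. MpPR15c was at -4.54 ± 0.44 and MpNBS-LRR20 at -3.82 ± 0.13. Pentatricopeptide repeat genes were higher in 29 of 71 by small amounts (median 0.12, camera adjusted p = 0.018 and adjusted p = 0.724 with an estimated correlation).

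In gata1-2 at growth light LEA genes were higher in 51 of 65 and lower in 3, with a median log2 fold change of 3.47 (camera adjusted p = 3.7e-14 and adjusted p = 0.712 with an estimated correlation). MpDHN1 stood at 81.8 ± 14.8 CPM at t0 against 6.06 ± 2.07 in BoGa, a log2 fold change of 4.13 ± 0.24 (SE) over both times, and MpLEA1 was at 4.35 ± 0.30. The catalase gene MpCAT1 was higher by 4.19 ± 0.30. Genes of tetrapyrrole and chlorophyll synthesis were lower in 6 of 7 (6 adjusted over the list alone, camera adjusted p = 0.049 and adjusted p = 0.712 with an estimated correlation), by small amounts: MpCHLD, a magnesium chelatase subunit gene, at -0.38 ± 0.06, MpGUN5, the gene of another subunit, at -0.46 ± 0.10, and MpHY1, a heme oxygenase gene, at -0.54 ± 0.08. MpLOX16 was at -7.26 ± 0.27 and MpPOD92 at -4.62 ± 0.25. Pathogenesis-related genes were lower in 14 of 29 (camera adjusted p = 0.023) and cupin genes in 27 of 67 (camera adjusted p = 0.038), each at adjusted p = 0.724 with an estimated correlation. In total 7985 genes differed, 4195 higher and 3790 lower, and 5413 with the t0 libraries alone.

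Both mutant lines differed from BoGa in the same direction in 4689 genes at growth light, 2489 higher and 2200 lower, and in opposite directions in 410. Independent lists would share 1048 and 909 and disagree in 1953. With the t0 libraries alone 2678 genes went the same way in both lines. These comparisons share the BoGa libraries. The observed covariance of log2 fold changes was 0.41. In 20 simulations of unchanged lines that shared simulated BoGa libraries it was 0.021 on average and 0.023 at most. The simulations drew all 36 libraries anew from the spread within groups, so they leave out a difference common to all BoGa libraries. With separate BoGa libraries for each line, 2530 and 2705 genes were shared and the covariance was 0.37 and 0.34. In high light 4066 genes were shared (1872 higher and 2194 lower, where independent lists would share 1031 and 1070) and 551 went in opposite directions, with a covariance of 0.46 against a simulated 0.041. Fits on the compared libraries alone shared 1608. The 3 BoGa libraries in high light are too few to divide, so each line could not be given its own there.

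In GATA1ox at growth light LEA genes were lower, 42 of 65 with 2 higher (median -1.78, camera adjusted p = 4.1e-07 and adjusted p = 0.724 with an estimated correlation). MpLEA1 stood at 0.48 ± 0.38 CPM at t0 against 12.03 ± 4.15 in BoGa, a log2 fold change of -3.82 ± 0.37 (SE) over both times. Oil body genes were lower in 7 of 25 and higher in 2 (the same adjusted over the list alone, camera adjusted p = 0.047 and adjusted p = 0.724 with an estimated correlation), with the terpene synthase-like genes MpFTPSL6 at -2.77 ± 0.16 and MpFTPSL3 at -1.60 ± 0.13. Phenylpropanoid genes were lower in 22 of 64 and higher in 7 (the same adjusted over the list alone, camera adjusted p = 0.049 and adjusted p = 0.724 with an estimated correlation), and pentatricopeptide repeat genes were higher in 20 of 71 (median 0.11, camera adjusted p = 0.044 and adjusted p = 0.724 with an estimated correlation). The peroxidase gene MpPOD80 was at 3.16 ± 0.20 and the zinc finger gene MpC2H2-21 at 3.07 ± 0.19. MpCYP829-like38 (Mp7g09860), a cytochrome P450 gene, stood at 11.2 CPM at t0 against 0.060 CPM in BoGa. In total 5247 genes differed, 2596 higher and 2651 lower. With the t0 libraries alone 3668 were called, and with the t6LL libraries alone, where GATA1ox and BoGa lay in different lanes, 2579.

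**Figure D4:**
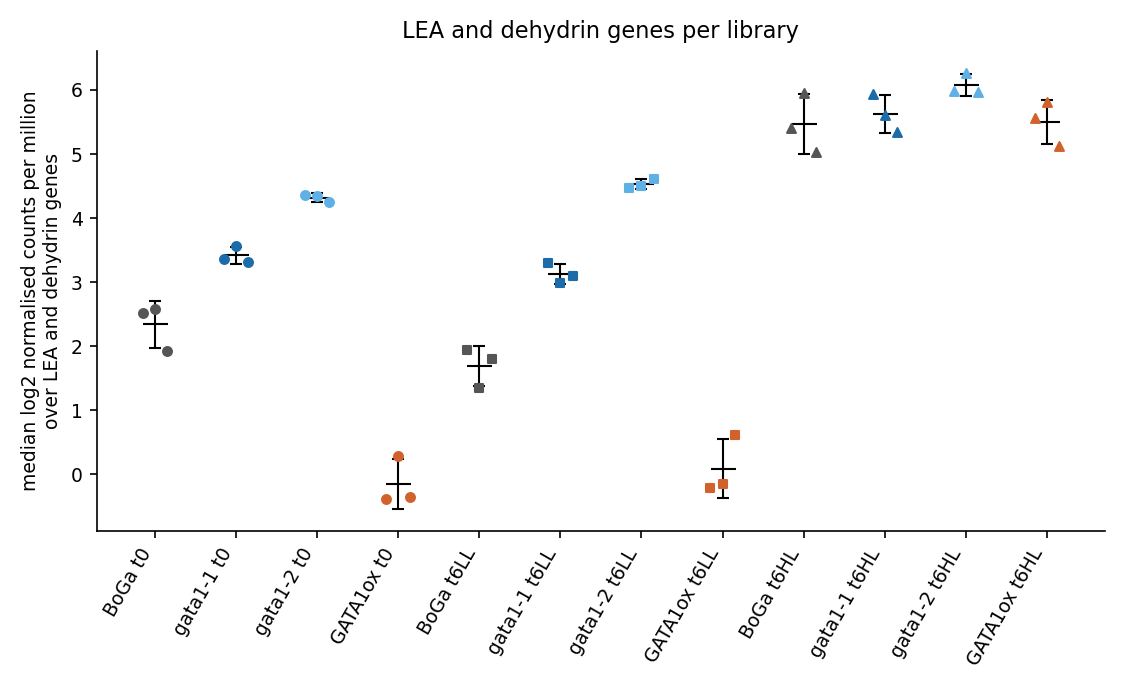
Median log2 normalised CPM over the LEA and dehydrin genes in each library (points), with the group mean and SD (black), by line and treatment. At t0 the libraries lay between 4.24 and 4.37 in gata1-2 and between -0.39 and 0.29 in GATA1ox, and in high light all lay between 5.03 and 6.27.

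In high light itself, where all libraries lay in lane 2, 9287 genes differed between gata1-1 and BoGa (4652 higher, 4635 lower), 7050 for gata1-2 (3452, 3598) and 4276 for GATA1ox (2131, 2145). Fits on the compared libraries alone called fewer: 5370, 3744 and 1067. The full fit uses a common spread per gene, although replicates differed more within t6HL groups than within t6LL groups. Its p-values in high light and in the interactions may therefore be too small, which was not tested. Genes of tetrapyrrole and chlorophyll synthesis were lower in gata1-1, 6 of 7 (6 adjusted over the list alone, camera adjusted p = 0.033 and adjusted p = 0.712 with an estimated correlation), with MpCHLD at -1.10 ± 0.09 and MpGUN4 at -1.16 ± 0.24. In GATA1ox 2 of 7 were higher (2 adjusted over the list alone, camera adjusted p = 0.048 and adjusted p = 0.712 with an estimated correlation), namely MpHY2, a phytochromobilin synthase gene, at 0.94 ± 0.15, and MpGUN5 at 0.41 ± 0.14. The MpGUN5 call was lost without BoGa t6HL replicate 1 (0.41, adjusted p = 0.067), BoGa t6HL replicate 3 (0.29, adjusted p = 0.17) or GATA1ox t6HL replicate 1 (0.24, adjusted p = 0.24). Lipoxygenase and jasmonate genes were lower in gata1-1 in 12 of 19 (12 adjusted over the list alone) and in GATA1ox in 7 (7 adjusted over the list alone), each at camera adjusted p = 0.032 and adjusted p = 0.712 with an estimated correlation. Oil body genes were lower in 16 of 25 in gata1-2 (17 adjusted over the list alone, camera adjusted p = 0.0022 and adjusted p = 0.712 with an estimated correlation) and in 12 in gata1-1 (12 adjusted over the list alone, camera adjusted p = 0.047 and adjusted p = 0.724 with an estimated correlation). MpRLK-Pelle_WAK1 (Mp3g01920), a receptor-like kinase gene, was lower in all 3 lines, at 0.30 CPM in gata1-1, 0.036 in gata1-2 and 0.090 in GATA1ox against 11.2 in BoGa (edgeR adjusted p = 3.3e-12, 9.8e-14 and 3.3e-13).

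Other lists in high light were called in single lines. In gata1-1 phenylpropanoid genes were lower in 29 of 64 (29 adjusted over the list alone, camera adjusted p = 0.039 and adjusted p = 0.724 with an estimated correlation). In gata1-2 polyphenol oxidase genes were lower in 24 of 51 (25 adjusted over the list alone, camera adjusted p = 0.013 and adjusted p = 0.724 with an estimated correlation) and class III peroxidase genes in 43 of 128 (43 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.051 with a replicate block and adjusted p = 0.836 with an estimated correlation). Pathogenesis-related genes were lower there in 17 of 29 (camera adjusted p = 0.0013) and cupin genes in 31 of 67 (camera adjusted p = 0.018), while fatty acid desaturase genes were higher in 7 of 13 (camera adjusted p = 0.020), each at adjusted p = 0.712 with an estimated correlation. LEA genes were higher there in 26 of 65 and lower in 5 (median 0.47, camera adjusted p = 0.00068 and adjusted p = 0.74 with an estimated correlation). The LEA list was not called in gata1-1 (median 0.32, camera adjusted p = 0.206) or GATA1ox (median 0.13, camera adjusted p = 0.824), where 15 and 4 members were higher and 7 and 10 lower. With 1 library left out the median ran from 0.10 to 0.47 in gata1-1 and from -0.0096 to 0.29 in GATA1ox. For gata1-1 the 15 became 8 with fits on the compared libraries alone and 26 without BoGa t6HL replicate 2, and the 7 became 14 without gata1-1 t6HL replicate 1. For GATA1ox the 10 lower became 5 with fits on the compared libraries alone. Its counts became 13 higher and 4 lower without BoGa t6HL replicate 2, and 6 were lower without GATA1ox t6HL replicate 3. In GATA1ox NBS-LRR genes were lower in 7 of 17 (camera adjusted p = 0.038 and adjusted p = 0.712 with an estimated correlation).

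Whether a line responded to high light differently from BoGa was tested as an interaction. In gata1-2 the LEA genes rose less than in BoGa, from a higher level: 43 of 65 had a smaller response, with a median difference of -2.34 (camera adjusted p = 2.1e-23 and adjusted p = 0.712 with an estimated correlation). The list median against BoGa was 3.58 at t6LL and 0.47 in high light. MpDHN1 differed in its response by -4.05 ± 0.44 (SE), the gene having been higher by 4.13 at growth light, and MpLEA-like50 by -2.28 ± 0.25. Oil body genes had a lower response, 10 of 25 (13 adjusted over the list alone, camera adjusted p = 3.7e-06 and adjusted p = 0.712 with an estimated correlation), with MpFTPSL1 at -1.68 ± 0.33. Glycosyltransferase genes had one too, 6 of 32 (6 adjusted over the list alone, camera adjusted p = 0.012 and adjusted p = 0.712 with an estimated correlation), with MpUGT28 at -1.36 ± 0.23. Class III peroxidase genes had a lower response in 9 of 128 (9 adjusted over the list alone, camera adjusted p = 0.0059 and adjusted p = 0.776 with an estimated correlation), and the polyphenol oxidase list moved down as a whole (median -0.50, camera adjusted p = 0.038 and adjusted p = 0.724 with an estimated correlation). Of the added lists autophagy (2 higher of 20, camera adjusted p = 0.0048), dirigent (4 lower of 48, camera adjusted p = 0.038) and pentatricopeptide repeat genes (4 higher of 71, camera adjusted p = 0.038) were called, each at adjusted p = 0.724 with an estimated correlation. In total 1099 genes were called, 389 with a higher and 710 with a lower response. The count fell to 677 without gata1-2 t6LL replicate 1, 654 without gata1-2 t6LL replicate 2 and 726 without gata1-2 t6HL replicate 3. With t0 as the baseline, which places both baselines in lane 1, 550 were called, and with a fit on the compared libraries alone 626.

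In GATA1ox the LEA genes rose more than in BoGa, from a lower level: 18 of 65 had a larger response, with a median difference of 1.62 (camera adjusted p = 2.0e-10 and adjusted p = 0.712 with an estimated correlation). MpLEA-like2 differed by 2.96 ± 0.50 (SE), from 0.37 to 47.4 CPM in GATA1ox and from 3.54 to 57.6 CPM in BoGa. The 18 became 5 with a fit on the compared libraries alone, 29 with t0 as the baseline, 9 without BoGa t6LL replicate 1, 10 without GATA1ox t6LL replicate 1 and 9 without GATA1ox t6LL replicate 2. MpC2H2-21 differed by -2.67 ± 0.35, the gene having been higher in GATA1ox at growth light. The bHLH list was called as well (median -0.19, camera adjusted p = 0.045 and adjusted p = 0.724 with an estimated correlation). In total 228 genes were called, 125 higher and 103 lower, and 445 with t0 as the baseline. The count became 132 without BoGa t6LL replicate 1, 147 without BoGa t6LL replicate 3, 107 without GATA1ox t6LL replicate 1 and 130 without GATA1ox t6LL replicate 2. It rose to 550 without BoGa t6HL replicate 2 and 353 without GATA1ox t6HL replicate 1. A fit on the compared libraries alone called 72. DESeq2 called 459, of which 47.9% were higher against 54.8% by edgeR.

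In gata1-1, where the lanes of both lines match at each time, 4086 genes had a response that differed from that of BoGa, 1771 higher and 2315 lower. A fit on the compared libraries alone called 2489. Of 29 genes that remove reactive oxygen species 11 had a lower and 4 a higher response (11 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.062 and adjusted p = 0.712 with an estimated correlation). Among the 11, MpGPX2 differed by -1.37 ± 0.16 (SE), MpPRX1 and MpPRX3 by -0.91 ± 0.13 and -0.97 ± 0.15 and the superoxide dismutase gene MpCSD by -0.79 ± 0.16. MpGPX2 went from 80.8 to 75.2 CPM in gata1-1 and from 66.04 to 158 CPM in BoGa. The oil body regulator MpC1HDZ differed by -1.99 ± 0.34 and the cyclin D gene MpCYCD_1 by -3.72 ± 0.61. Of 128 class III peroxidase genes 12 had a lower response and 1 a higher one (4 and 1 adjusted over the list alone, camera adjusted p = 0.049 and adjusted p = 0.836 with an estimated correlation). The call of this list was lost with a replicate block. The list's share of genes with a lower response was below that over all tested genes (2315 of 15583). LEA genes had a lower response in 22 of 65 (median -0.91, camera adjusted p = 0.038 and adjusted p = 0.829 with an estimated correlation). They rose from a higher level than in BoGa, the list median against BoGa being 1.13 at t6LL and 0.32 in high light. That 22 became 13 with a fit on the compared libraries alone, 12 with t0 as the baseline, 12 without BoGa t6LL replicate 2, 13 without BoGa t6HL replicate 2 and 14 without gata1-1 t6HL replicate 3. The median of -0.91 ran from -1.10 to -0.55 with 1 library left out. Among the GATA genes the response of MpGATA4 differed by -1.32 ± 0.30 (edgeR adjusted p = 0.0024) in gata1-1 and by 0.99 ± 0.30 (edgeR adjusted p = 0.10) in GATA1ox, where DESeq2 called it (0.97, adjusted p = 0.043).

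The 6 h at growth light between t0 and t6LL changed 238 genes in BoGa, 61 higher and 177 lower, of which 50 changed at least 2-fold. A fit on the compared libraries alone called 4144. The count also depended on single libraries. Without BoGa t0 replicates 1, 2 or 3 it was 1, 0 and 76 by edgeR (2060, 1878 and 2277 at an unadjusted p under 0.05), and without BoGa t6LL replicates 1, 2 or 3 it was 10, 5 and 2. DESeq2 called 731 genes with all libraries. Class III peroxidase genes were lower in 10 of 128 (34 adjusted over the list alone, camera adjusted p = 3.7e-14) and cytochrome P450 genes in 3 of 105 (5 adjusted over the list alone, with 1 higher, camera adjusted p = 0.00020), each at adjusted p = 0.712 with an estimated correlation. Nitrate and ammonium transporter genes were lower in 1 of 32 (1 adjusted over the list alone, camera adjusted p = 0.022 and adjusted p = 0.712 with an estimated correlation), the ammonium transporter gene MpAMT2.2. Expansin (median -0.30, camera adjusted p = 0.014), polyphenol oxidase (median -0.32, camera adjusted p = 0.00070), cupin (median -0.44, camera adjusted p = 0.00057) and dirigent genes (median -0.33, camera adjusted p = 0.00012) moved down as lists and pentatricopeptide repeat genes up (median 0.14, camera adjusted p = 4.3e-08), each at adjusted p = 0.712 with an estimated correlation. Oil body (median -0.32, camera adjusted p = 0.013), autophagy (median 0.14, camera adjusted p = 0.011) and fatty acid desaturase genes (median -0.19, camera adjusted p = 0.046) were at adjusted p = 0.724 with an estimated correlation, and LEA genes (median -0.48, camera adjusted p = 0.0039) at adjusted p = 0.771 with an estimated correlation. The same step called 0 genes in gata1-1 by edgeR (385 at an unadjusted p under 0.05, 2 by DESeq2), 2 in gata1-2 and 139 in GATA1ox. The difference of this step from BoGa, which in gata1-2 and GATA1ox crosses the lanes, called 0 genes by edgeR in each line. At an unadjusted p under 0.05 it held 1519, 999 and 873 genes, and DESeq2 called 108, 36 and 9.

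Across the 14 comparisons and 32 lists, 73 of 448 list tests were called with the preset correlation, 19 up and 54 down. With an estimated correlation limma's camera called 0 of them (26 at an unadjusted p under 0.05), while fry, which asks whether a list moves on balance 1 way, called 64 of the 73 and 223 in all. Lists called in none of the 14 comparisons were those of the AP2/ERF, MYB and GATA transcription factors, auxin and cytokinin, light signalling, glutathione transferases, ABC transporters, 2-oxoglutarate dioxygenases and O-methyltransferases.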

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

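All tests with other splits of the libraries, and those of shared BoGa values, of lanes and of a weaker response for the LEA genes, were chosen only after the results were seen; the test of a BoGa-like response by its median was written before, and its shares were added after.

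A test of the difference between lines found genes whose response to high light differed from that of BoGa: 4086 in gata1-1, 1099 in gata1-2 and 228 in GATA1ox (2489, 626 and 72 in fits on the compared libraries alone). Among 100 splits of the same libraries, 6 gave as many calls for gata1-1 (highest other 3097), 5 for gata1-2 (highest other 2216) and 3 for GATA1ox (highest other 534). For gata1-2 and GATA1ox the highest other split called several times the real count. The others that called as many, 5, 4 and 2 in number, all exchanged most line labels in 1 treatment alone, which turns the line difference itself into an interaction. These counts therefore do not decide whether chance is excluded in any of the 3 lines.

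For the line differences at growth light, fits on the compared libraries alone called 10488 genes for gata1-1 (highest other 3979), 10025 for gata1-2 (4457) and 7204 for GATA1ox (1124). In each line 1 of 100 splits, the real one, gave as many calls, so a chance division of these libraries is argued against. The labels do not name separate cultures, so differences between cultures are not excluded by this. Fits on the compared libraries alone also gave 8346, 9506, 8673 and 8456 calls for the responses to high light in BoGa, gata1-1, gata1-2 and GATA1ox. They gave 5370, 3744 and 1067 for the line differences in high light and 4144 for the mock response. For all of these, 10 splits are too few for a share under 0.05. In each of these the real split was the 1 with the most calls, and the highest other called 0 genes by edgeR, which for gata1-2 in high light includes the splits that part the same pairs of replicate numbers.

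LEA and dehydrin genes at growth light were higher in both mutant lines and lower in GATA1ox, and high light brought the lines closer together. Chance values of the shared BoGa libraries cannot be the source of the gap between the lines, which was also there without BoGa. In the list median of log2 CPM the lowest growth light library of a mutant line lay 2.37 above the highest of GATA1ox. Libraries within a line ranged over at most 1.01. The direction of this gap follows from the pattern, so it leaves open how far each line differed from BoGa. The 13.8% of the list with the same sign in gata1-2 and GATA1ox likewise restates the pattern and decides nothing. A difference between lanes is argued against by the t0 libraries alone, all from lane 1, which kept 91.5% or more of the medians of gata1-2 and GATA1ox. A full response like that of BoGa in high light is argued against by the 2234 genes outside the list that BoGa raised at least 2-fold: their median was 0.17 in gata1-2 and -0.07 in GATA1ox, and 33.5% were called higher in gata1-2 and 20.7% lower in GATA1ox. A weaker or partial form of that response stays open: of those genes called, 73.8% (748 of 1014) were higher in gata1-2 and 66.4% (462 of 696) lower in GATA1ox. In gata1-1 691 were called higher and 288 lower. Its median of 0.177 was close to the 0.175 of gata1-2, although the LEA medians were 1.04 and 3.47, so this measure did not follow the LEA change. The genes were picked with the BoGa t6LL libraries that also serve as a baseline here, which favours higher values in the lines. An effect of B-GATA1 on the LEA genes also stays open. Plant age, water status and line background were not tested, and the list's test is not called with an estimated correlation.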

How the results depend on the processing

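Exon reads, autosomal genes alone, leaving out MpVg01240, most settings applied to the shared calls, the replicate block for the list tests and the offset of the response size were chosen after seeing the data; the other alternatives were planned.

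Of the alternatives to the counts and sizes, 284 kept their direction and side of the threshold, or for a count stayed within 1.5 times, while 41 were weaker, 7 stronger and 9 sizes moved by more than the spread between replicates. Of the alternatives to the named genes and lists, 8094 did so, 392 lost a call, 8 gained 1 and 13 reversed.

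With a fold of at least 2 the responses to high light held 3371 (BoGa), 4886 (gata1-1), 3910 (gata1-2) and 3677 genes (GATA1ox). The line differences at growth light held 1637, 1859 and 1327 in gata1-1, gata1-2 and GATA1ox, those in high light 3201, 2179 and 1172, the interactions 1270, 516 and 149, the mock response 50, and the shared calls 733 at growth light and 867 in high light. This follows from the stricter threshold. In genes that changed at least 2-fold in the mean, the response size was 1.83 and -1.22 in BoGa, 2.41 and -1.52 in gata1-1, 1.64 and -1.59 in gata1-2, and 1.86 and -1.36 in GATA1ox, which follows from the choice of genes. With RLE factors the size for the falling genes of gata1-1 was -0.60; the cause was not tested.

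Fits on the compared groups alone called 5370, 3744 and 1067 genes in high light, 2489, 626 and 72 in the interactions, 4144 in the mock response and 1608 shared in high light. At growth light they called more than the full fit: 10488 against 7631 in gata1-1, 10025 against 7985 in gata1-2 and 7204 against 5247 in GATA1ox. These fits have fewer libraries to estimate the spread from. The full fit uses a common spread per gene for all groups. The chi-square per gene between replicates was 24.8 to 333 within t6HL groups and 4.63 to 22.4 within t6LL groups. At t0 it was 7.05 to 25.4, except in GATA1ox with 135 to 910. P-values of the full fit may therefore be too small in high light and too large at growth light. The cause of the lower and of the higher counts was not tested. With t0 alone 5057 genes differed in gata1-1 and 2678 were shared, and with t6LL alone 2579 differed in GATA1ox, each from fewer libraries. With t0 as the baseline the interactions called 550 in gata1-2 and 445 in GATA1ox; the cause was not tested. DESeq2 called 459 genes in the interaction of GATA1ox and 731 in the mock response, of which 40.4% were higher against 25.6% by edgeR; the cause was not tested. Of the gene list tests, camera with an estimated correlation called 0 (26 at an unadjusted p under 0.05) and fry called 223, since fry does not compare a list with other genes.

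Leaving out 1 library at a time gave 8261 to 8947 genes for the response to high light in BoGa, 10417 to 10911 in gata1-1, 9035 to 9717 in gata1-2 and 8683 to 9554 in GATA1ox. At growth light the ranges were 7014 to 7227, 7473 to 7726 and 4428 to 5000 for gata1-1, gata1-2 and GATA1ox, and in high light 7952 to 9438, 5875 to 6874 and 3347 to 4480. The interactions gave 2954 to 5165, 654 to 1400 and 107 to 550. The mock response gave 0 to 76, the 0 by edgeR without BoGa t0 replicate 2 (1878 at an unadjusted p under 0.05). The shared calls gave 4216 to 4556 and 3072 to 4290.

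Reversed values were of small changes or of the t0 baseline. With t0 as the baseline the interaction of gata1-1 was 0.017 for MpPOD52, 0.072 for MpPOD81 and 0.077 for MpFTPSL1. The interaction of gata1-2 for MpGATA4 was 0.017 with exon reads, 0.002 without MpVg01240 and -0.236 to 0.204 with 1 library left out. That for MpGATA1 ran from -0.143 to 0.046. The high light response of MpGATA4 in GATA1ox ran from -0.259 to 0.090. For MpGATA1 in GATA1ox the difference in high light ran from -0.129 to 0.011 and the interaction from -0.126 to 0.013. The cause was not tested.

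With library size alone as the scaling, the median of all genes moved to -0.14 in the interactions of gata1-1 and gata1-2. In 28 of 29 pairs of groups, of the same or of different times, not all 3 correlations of same-numbered libraries were above 0.1 (median over all pairs -0.01). The exception was BoGa and gata1-2 at t6HL. The replicate block ran over all times, so a pairing within a time point was not modelled. With a replicate block the 14 counts stayed within 1.5 times and no named gene changed its call. Of the lists, class III peroxidase genes lost their call in gata1-2 in high light (adjusted p = 0.051) and in the interaction of gata1-1 (adjusted p = 0.058). A call was gained by 2-oxoglutarate dioxygenase genes in gata1-1 at growth light (adjusted p = 0.045) and dirigent genes in GATA1ox in high light (adjusted p = 0.037). In simulated data 1.5-fold changes were recovered in 56.7% of genes for a response to high light, 59.7% for a line difference and 32.8% for an interaction. Only 67 of 15583 genes were changed by that fold in each simulation, where 9288 were called in the real response of BoGa. The adjustment of p is stricter where few genes change, so these shares do not carry over to the data. Depth was not varied in the simulation either, and the chi-square per gene between replicates was 4.63 to 910, where counting noise gives 1.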

Other observations

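The tests of U-linked expression, of opposite B-GATA1 activity and of a shared background, their exact intervals and the measure without MpVg01240 were chosen only after the results were seen; the covariance test was written before. The test of shared BoGa libraries by high light was also chosen after, as was the rule that an interval holding the limit leaves a share open.

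At growth light 398 genes differed from BoGa at least 2-fold in all 3 lines. Of these, 189 were higher in both mutant lines and lower in GATA1ox, 21 the reverse, 151 went the same way in all 3 and in 37 the mutant lines parted. Among the 189 were 32 LEA and dehydrin genes, a count that restates the changes of that list in the 3 lines. Another 16 had names, among them MpCALEOSIN, MpPP2C_A3, MpDHAR4 and MpIAR4B, chosen after their values were seen. Mp7g01940 (chromosome 7, 2581293 to 2588456), also chosen after its values were seen, stood at 14530 ± 543 CPM in gata1-1 and 6908 ± 441 in gata1-2 at t0, against 401 ± 24.2 in BoGa and 500.3 ± 15.8 in GATA1ox (mean ± SD, n = 3).

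The gata1-1 libraries expressed U-linked genes. Reads shared between copies on U and V are argued against, since 30 U-linked genes or more passed 1 CPM in each gata1-1 library with uniquely placed reads, and so are libraries swapped between groups, with 0 out of place. A mixture with plants of the other sex was first measured by V-linked expression, which in gata1-1 reached 162% of the lowest BoGa library, but MpVg01240 made up 98.1 to 99.0% of it, so that measure was void. Without that gene it was 6.19%, which argues against a large mixture. A small share of RNA from plants of the other sex is not excluded. A female plant as the source of the line is a candidate explanation that stays open, and effects of sex and of the mutation cannot be told apart in gata1-1 by these libraries.

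The 3 lines also shared changes from BoGa, which the shared BoGa libraries alone might cause. As the cause of the whole pattern they are argued against by the lower covariance of GATA1ox with a mutant line, 0.10, above the highest simulated 0.024, and by high light, whose libraries are others: of the 151 genes 71 were called at least 2-fold the same way again in all 3 lines and 1 the opposite way (98.6% the same way), where 1.76 would be called either way if independent (genes are not independent replicates). With separate BoGa libraries the covariance, which over all genes also holds the opposite changes, ran from 0.00080 to 0.13, so a share due to these libraries was not measured. Opposite B-GATA1 activity in mutants and GATA1ox would move a gene opposite ways. By this definition it does not account for the 151 genes that went the same way, where independent lists would share 4.1. They were picked for that direction, so they are no test of opposite activity. Whether the lines have opposite B-GATA1 activity was not measured. For the 210 genes with the mutant lines one way and GATA1ox the other this explanation stays open. The share of genes going the same way in all 3 lines, 37.9% (exact 95% interval 33.2 to 42.9%), lay under the limit of 50%. Unrelated lists would give 24.5%, so that limit decides nothing. A background that BoGa does not share with the other lines was read from the genes that kept their call and direction in high light, 47.0% (38.9 to 55.3%), an interval that holds the limit of 50%, so it stays open.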
